A study of Lactiplantibacillus plantarum WCFS1 with 12 samples.

How the data were processed

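Total RNA of 8 samples of Lactiplantibacillus plantarum WCFS1 was labelled with Cy3 or Cy5 by reverse transcription and hybridised in pairs on 12 2-colour arrays, per the labels' protocols. Each sample is called a culture here, although the design text takes same-numbered control and shock samples from the same batch culture. Conditions, dyes and replicate numbers were taken from the labels of both channels. Each culture was hybridised on 2 or more arrays in loops without a common reference, so the culture, and not the array, was the replicate. The design text names duplicate cultures for each condition. The labels give no slide, batch or scan for any array, so no batch was tested.

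The deposited scanner files hold the intensity of each spot and of its local background in both channels, written by the ImaGene image software per the file headers, with channel 1 for Cy3 and channel 2 for Cy5. These intensities were not background-subtracted or normalized. The software version, the scanner and the genome build are not given in the sources used here. A deposited table of the series holds log2 ratios per spot, and its processing is not given in the sources used here. Compared with the scanner values, each of these log2 ratios equalled the log2 of Cy3 over Cy5 after subtraction of the background median, with a largest difference of 0 at 4 decimals on every array. The column medians of the deposited log2 ratios were between 0.06 and 0.49, so they were neither centred nor corrected for intensity. They served as an alternative with the sign turned and each array centred on its median.

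The 10807 spots of an array comprised 9553 spots of 7968 locus probes, 54 spots of other features, 656 blanks, 89 negative controls and 455 other control spots. Signal medians were corrected by the background medians with normexp at an offset of 50 on all spots, and log2 Cy5 over Cy3 was normalized by loess within each array, with control spots at weight 0. Spots were averaged per probe and probes per locus. Of the 2851 loci, 2675 had more than 1 probe. A locus was tested when a probe of it exceeded the 95th percentile of the negative controls in at least 0.5 of the channels that held 1 of the conditions, and all 2851 did; 2841 did so in every channel. No spot was left out for saturation, which affected 0 to 4 locus spots per channel. Spot flags of channel 1 marked 95 to 277 locus spots per array as empty and 330 to 486 as negative. These spots were kept, and fits without them were not run.

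Least squares over all arrays, with 1 dye term, turned the ratios into a log2 level per culture. In the second step limma (lmFit and eBayes) was run on the 8 culture levels with 1 coefficient per condition. It leaves 4 residual degrees of freedom shared by all conditions and 3.57 prior degrees of freedom. This step takes the 8 levels as independent and equally precise, although they were fitted jointly and share the error of arrays. An alternative with culture as a random effect fitted the array ratios and put culture variance at 0.329 of array variance. It called 259 loci at 10 min, 309 at 30 min and 4 at 30 over 10 min. In adapted over control it called 736, and in adapted over 30-min shock 0. Adjusted p values are Benjamini-Hochberg values over the 2851 loci, two-sided, with a threshold of 0.05. The 5 comparisons were 10-min shock over control, 30-min shock over control, 30-min over 10-min shock, adapted over control and adapted over 30-min shock. Correlations of fold changes were set against 100 simulated draws of unchanged cultures with the same spread per locus and shared controls. Cultures were drawn independently, so the batch culture shared by control and shock samples was not simulated. The arrays and the least squares step were not simulated either, so error that fitted levels share through arrays is absent from the simulated values. Tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with matplotlib 3.10.9 for the plots.

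Conditions, the limma tests, the correlations of fold changes, gene lists, the rule for named loci and all alternatives apart from 3 were fixed before the data were examined. The rule takes, per comparison, up to 10 rising and 10 falling loci with the largest change among those past the threshold whose 2 cultures of one condition both lie on the same side of the other 2. Since the files do not pair locus tags with gene names, only the top 2 in each direction are given. The reference gene table at hand belongs to another strain, SRCM100442, and 0 of the locus tags matched it. Of 25 gene lists, 24 had no member that could be matched, and camera and fry were not run on these lists. Camera was run on 1 group of loci, those with the mark p3 in their tags, chosen after the data were seen. The remaining list, heat shock genes, contained 3 members entered by locus tag as small heat shock genes (lp_0129, lp_2668 and lp_3352), a pairing that no table used here gives. Adjustment of p values over these 3 loci alone was not part of the plan, which set camera and fry for the lists. The stress regulator and chaperone genes that the rule would add by name were not matched and are not analysed here. All 4 loci that passed at 30 over 10 min are given, and the 3 loci with opposite changes under short and long exposure were chosen after their values were seen.

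The pairing of the replicate numbers was checked by the correlation across loci of the culture 1 minus culture 2 differences. It was 0.27 for control with 10-min shock, 0.64 for control with 30-min shock and 0.33 for 10-min with 30-min shock, and −0.63, −0.22 and −0.67 for the adapted cultures with these 3. Without arrays 9 and 11 the values were 0.50, 0.34 and 0.59, and −0.15, 0.03 and 0.19. Most arrays joined samples of the same number, so array error shared by fitted levels can make these differences correlate by itself. The check therefore cannot tell a shared batch culture from the layout of the arrays. The design text takes control and shock samples of one number from the same batch culture, so the labels pair these. The fit behind the counts has no block, as fixed beforehand, and so treats these samples as independent. With the replicate block over control and shock cultures, limma called 420 loci at 10 min (387 shared with the fit without it), 392 at 30 min (354 shared), 4 at 30 over 10 min (4 shared), 761 in adapted over control (713 shared) and 473 in adapted over 30-min shock (380 shared). Beside results it is given only for named loci whose call it changed.

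The fit was tested on simulated data with 200 of 2851 loci changed. It recovered 66% (adapted over control) to 77% (30-min shock over control) of loci changed 1.5-fold, and 97.5% (adapted over 30-min shock) to 100% of those changed 2-fold. False calls were 3.85% to 8.02% over simulated changes of 1.5-fold, 2-fold and 4-fold. The simulation used correctly labelled arrays, with array noise and culture spread taken from the fit without arrays 9 and 11. The residual SD of that fit was 0.0806, against 0.263 with all 12 arrays. The simulated rates therefore describe cleaner data than the 12 arrays as labelled. With no locus changed, 0 to 2 loci were called per comparison.

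Alternatives changed the background correction, the normalization within and between arrays, the source of the values, the filter, the summary of probes, the dye term, the replicate block, the cultures in the fit, the prior variance and the unit of replication, and left out each culture and each array in turn, where the lone remaining culture of a condition is taken to vary like the others. Normalizing mean intensities between arrays leaves ratios untouched by construction, and the filter removed no locus. After the data were seen, 3 were added: leaving out arrays 9 and 11, the same with the replicate block, and signal means in place of signal medians.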

Results

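Transcript levels of the lactic acid bacterium Lactiplantibacillus plantarum WCFS1 were compared on 12 2-colour arrays, each carrying Cy5-labelled cDNA of 1 RNA sample and Cy3-labelled cDNA of another. The 8 RNA samples came from 4 conditions with 2 cultures each: control without ethanol, control cultures given 8% ethanol and sampled after 10 min (10-min shock) or 30 min (30-min shock), and cultures grown with 8% ethanol (adapted). The labels describe the adapted cultures in more than 1 way, as adapted for 24 h in the sample titles, as a continuous culture in the design text and as a broth culture grown to a set density in the growth protocol. Same-numbered control and shock samples were time points of the same batch culture according to the design text. The array titles carry the numbers 1 to 12. Written as Cy5 over Cy3, array 1 joined control 1 and 10-min shock 1, array 2 joined 30-min shock 1 and control 1, array 3 joined 10-min shock 1 and 30-min shock 1, and array 4 joined control 1 and adapted 1. Array 5 joined adapted 1 and adapted 2, array 6 adapted 2 and 30-min shock 1, array 7 control 2 and adapted 1, and array 8 30-min shock 2 and control 2. Array 9 was labelled 30-min shock 1 over 30-min shock 2, array 10 was labelled 10-min shock 2 over 30-min shock 2, array 11 was the dye swap of array 10, and array 12 was labelled 10-min shock 1 over 10-min shock 2.

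The array measured 2851 loci with 1 to 3 probes each, and all 2851 lay above the negative control spots often enough to be tested. Median background-subtracted intensity of the locus spots was 376 to 578.5 per array in Cy5 and 428 to 651 in Cy3. The share of locus probes above the 95th percentile of the negative controls was 97.5% or higher in every channel. The number of cultures, 2 per condition, limits the precision. The SE and adjusted p values below take the fitted culture levels as independent, although these levels share arrays. The files give locus tags without gene names, and no table used here pairs these tags with names, so loci are given by tag and only a few are listed.

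On 10 arrays the measured ratios followed the ratios that the other arrays gave for the same labels, and on arrays 9 and 11 they did not. Pearson r across loci between measured and predicted ratios was 0.65 to 0.97 on the 10 arrays, −0.14 on array 9 and −0.13 on array 11. Array 9, labelled as the 2 cultures of the 30-min shock, had a log2 ratio SD of 0.54, against 0.34 and 0.25 on the arrays that joined the 2 adapted and the 2 10-min cultures. Its ratios correlated at r = 0.95 with those of array 6, labelled adapted 2 over 30-min shock 1. Array 11 correlated at r = 0.14 with its dye swap, array 10, where opposite signs of the same ratios were labelled, and at r = 0.87 with array 1, labelled control 1 over 10-min shock 1. The residual SD of the fit to the array ratios was 0.263 with 12 arrays and 0.0806 without arrays 9 and 11. All 12 arrays entered as labelled, and the number of called loci in each comparison below is followed by the number from the 10 other arrays, an alternative chosen after the data were seen. Fits below that leave out 1 culture or array start from the 12 arrays as labelled, so most still hold array 9 or 11.

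**Figure D1:**
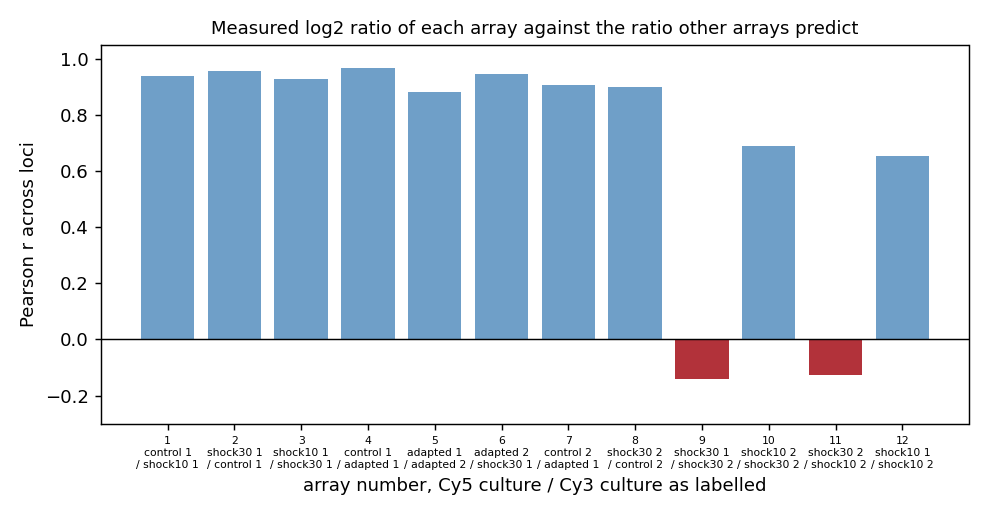
Pearson r across 2851 loci (vertical axis) between the log2 ratios of each of the 12 arrays (horizontal axis, with the labelled Cy5 and Cy3 cultures) and the ratios predicted for that label by the other arrays, arrays 9 and 11 never being used for prediction. Arrays 9 and 11 (red) lie at −0.14 and −0.13, and the lowest of the 10 others (blue) is at 0.65.

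The first question was how the cells answered to 10 min of ethanol. The labels name no sample kept without ethanol for 10 or 30 min. In both shock comparisons with control, elapsed time and handling may therefore differ along with ethanol. Of the 2851 loci, 425 differed from control, of which 207 rose and 218 fell. The 2 largest rises were at the adjacent loci lp_0746, at 54.4-fold (log2 5.77 ± 0.20 SE, 2 cultures per condition), and lp_0747, at 53.1-fold (log2 5.73 ± 0.18). Both had an adjusted p of 3.81e-06 by limma with Benjamini-Hochberg adjustment. The value of lp_0746 rests on 1 probe, and the 3 probes of lp_0747 ran from log2 5.50 to 6.13. The largest falls were at lp_2704 (log2 −2.45 ± 0.25, limma with Benjamini-Hochberg adjusted p = 0.00165) and lp_0256 (−2.17 ± 0.18, adjusted p = 0.000536). At all 4 loci both shocked cultures lay on the same side of both control cultures, which the rule for named loci requires. Changes of 2-fold or more made up 66 of the rises and 41 of the falls, and 46 and 20 without arrays 9 and 11. Among the 3 loci fixed beforehand as small heat shock genes, a family of chaperones that bind unfolding proteins, lp_3352 rose (log2 1.58 ± 0.24, limma with Benjamini-Hochberg adjusted p = 0.00615). The other members had log2 values of 1.07 ± 0.30 (lp_0129) and −0.25 ± 0.26 (lp_2668) and did not pass over all loci. The list names these loci by tag, and no table used here pairs the tags with genes. Adjusted over the list alone, a step not planned beforehand, 2 of the 3 rose. With the replicate number as a block over the control and shock cultures, lp_0129 passed over all loci as well (log2 1.07, limma with Benjamini-Hochberg adjusted p = 0.0163, range over 37 alternatives 0.00495 to 0.996), and without arrays 9 and 11 its log2 value was 0.51, which passed with the block and not without it. The 10 other arrays alone gave 389 loci, 194 higher and 195 lower, 357 of them shared with the 425. On these arrays lp_2704 stood at log2 −1.92, lp_0256 at −1.79 and lp_3352 at 1.12. The rises of lp_0746 and lp_0747 were smaller there, at log2 5.19 and 5.07. Both loci passed under all 37 alternatives, but their log2 values went from 3.83 (lp_0746) and 4.48 (lp_0747) without background correction to 6.79 and 7.01 without culture 1 of the 10-min shock. Calls were lost at lp_2704 without culture 2 of the 10-min shock or array 12, at lp_0256 without control culture 2, and at lp_3352 without any 1 of these 3 or of array 5 and with culture as a random effect. With 1 culture or array left out, log2 ran from −3.68 to −1.59 for lp_2704, −2.62 to −1.53 for lp_0256 and 0.93 to 2.42 for lp_3352. The count fell to 8 without culture 2 of the 10-min shock, to 46 without control culture 2 and to 30 without array 12.

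**Figure D2:**
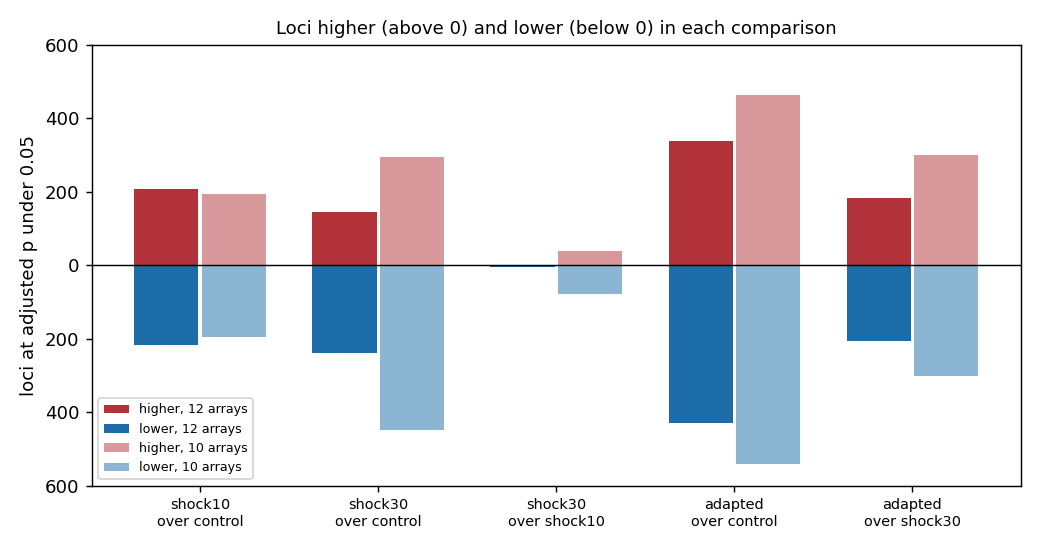
Number of loci at adjusted p under 0.05 (vertical axis) in each of the 5 comparisons (horizontal axis), with higher loci above 0 (red) and lower loci below 0 (blue); dark bars use 12 arrays as labelled and pale bars leave out arrays 9 and 11. Adapted over control has the most called loci, 767 with 12 arrays and 1004 with 10, and 30-min over 10-min shock the fewest, 4 and 117.

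The second comparison asked what remained or appeared after 30 min of ethanol. Relative to control, 383 loci differed, 145 higher and 238 lower. The locus lp_0749 rose 8.94-fold (log2 3.16 ± 0.18, limma with Benjamini-Hochberg adjusted p = 0.000354) and lp_1112 rose 6.35-fold (log2 2.67 ± 0.20, adjusted p = 0.000706). The value of lp_0749 rests on 1 probe. The largest falls were at lp_2700 (log2 −2.30 ± 0.23, limma with Benjamini-Hochberg adjusted p = 0.00143) and lp_2698 (−2.15 ± 0.24, adjusted p = 0.0022). Both 30-min cultures lay on the same side of both control cultures at these 4 loci, as the rule requires. Of the listed small heat shock loci, lp_0129 rose by log2 2.12 ± 0.30 and lp_3352 by 1.97 ± 0.24, with limma and Benjamini-Hochberg adjusted p of 0.00526 and 0.00321. For lp_2668 the log2 value was 0.00 ± 0.26. Adjusted over the list alone, the same number, 2 of 3, rose. Leaving out arrays 9 and 11 gave 741 loci, with 294 higher and 447 lower, and it contained all 383. Without background correction the rises were smaller, at log2 2.23 for lp_0749, 1.58 for lp_1112, 1.26 for lp_0129 and 1.48 for lp_3352. The falls were then −2.08 at lp_2700 and −2.00 at lp_2698, and all 6 loci still passed. Leaving out culture 1 of the 30-min shock or array 12 gave 0 loci in limma, with 441 and 547 loci at an unadjusted p under 0.05, and ended the call of each of the 6 loci named as changed here, whose log2 values without any 1 culture or array stayed between 1.46 and 3.69 in size.

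The 10-min and 30-min responses were set against each other to see how the shock response moved with time. Only 4 loci differed between 30 and 10 min at adjusted p under 0.05, all lower at 30 min and all in a row of tags: lp_0746, lp_0747, lp_0748 and lp_0749. Their log2 changes were −3.48 ± 0.20, −3.10 ± 0.18, −2.23 ± 0.15 and −2.22 ± 0.18. In limma with Benjamini-Hochberg adjustment the adjusted p values were 0.000363 for the first pair, 0.000709 and 0.00233. All 4 had risen at 10 min over control. No locus was higher at 30 min (0 in limma), and 222 loci had an unadjusted p under 0.05 in either direction. Of the small heat shock loci none of the 3 was called over all loci, and 1 rose when adjusted over the list alone; the log2 values were 1.04 ± 0.30 for lp_0129, 0.39 ± 0.24 for lp_3352 and 0.25 ± 0.26 for lp_2668. This comparison depended most on the doubted arrays: without arrays 9 and 11, 117 loci were called, 40 higher and 77 lower, with the same 4 among them, lp_0129 at log2 1.70 ± 0.17 and lp_3352 at 0.95 ± 0.18 also passing. The log2 changes of lp_0746, lp_0747, lp_0748 and lp_0749 were then −2.77, −2.32, −1.33 and −1.36, and without culture 2 of the 10-min shock −2.65, −2.11, −0.95 and −0.88. The count was 0 in limma without culture 2 of the 10-min shock, adapted culture 1 or array 12 (365, 107 and 93 loci at an unadjusted p under 0.05), 1 without culture 1 of the 30-min shock, and 2 without culture 1 of the 10-min shock or array 9. Only 2 of the 4 loci were among the 12 called without array 11, the 4 called without culture 2 of the 30-min shock and the 5 called with each array as a replicate, and only 1 among the 4 called with culture as a random effect.

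**Figure D3:**
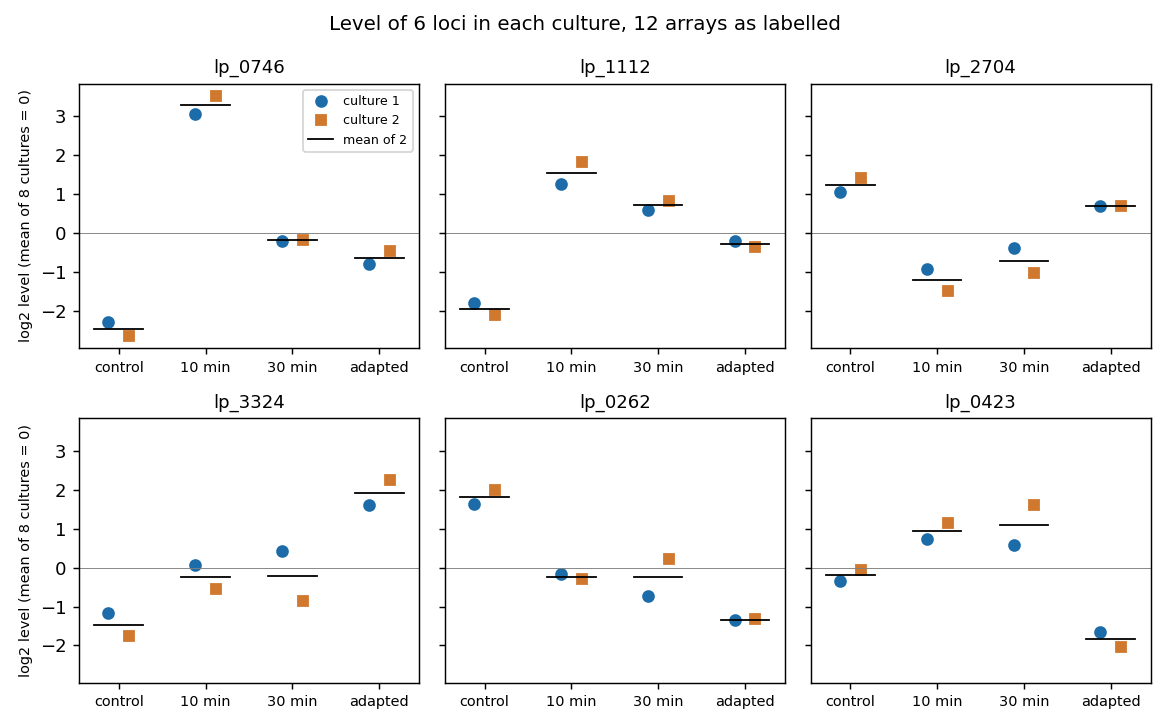
Fitted log2 level (vertical axis, relative to the mean of the 8 cultures) of 6 loci in culture 1 (circles) and culture 2 (squares) of each condition (horizontal axis), with black lines at the means of 2. The locus lp_0746 rises by log2 5.77 at 10 min and changes by −3.48 from 10 to 30 min, whereas lp_3324 is highest and lp_0262 lowest in the adapted cultures.

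Fold changes at 10 and 30 min against the shared controls correlated across the 2851 loci at Pearson r = 0.88 and Spearman rho = 0.85. Unchanged groups simulated against shared controls, without a shared batch culture or shared arrays, gave r = 0.50. The covariance was 0.205 against 0.0152 in the simulation. The comparisons shared 115 rising loci, where independent lists would share 10.5, and 146 falling loci, where they would share 18.2. Leaving out arrays 9 and 11 gave r = 0.82 and 154 and 169 shared loci, where 20.0 and 30.6 would be shared. No locus was called in opposite directions. Loci are not independent replicates, and the controls were not split, since no part would keep 2 cultures. Part of the excess may therefore come from the shared controls or from error of shared arrays.

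The adapted cultures, grown with ethanol, were compared with control; by one description they were continuous cultures and the controls batch cultures, so culture mode and growth stage may differ along with ethanol. In them 767 loci differed, 339 higher and 428 lower, and the changes of 2-fold or more were 101 rises and 108 falls (93 and 102 without arrays 9 and 11). The largest rises were at lp_3324, 10.5-fold (log2 3.39 ± 0.44, limma with Benjamini-Hochberg adjusted p = 0.00424), and lp_0995, 6.30-fold (log2 2.66 ± 0.53, adjusted p = 0.012). The adjacent loci lp_0263 and lp_0262 fell the most, with log2 −3.48 ± 0.40 and −3.16 ± 0.28 and limma Benjamini-Hochberg adjusted p of 0.00424 and 0.00191. Both adapted cultures lay on the same side of both control cultures at these loci, as the rule requires. Of the small heat shock loci, lp_2668 rose by log2 1.88 ± 0.26 and lp_3352 by 1.70 ± 0.24 (limma with Benjamini-Hochberg adjusted p = 0.00459 for each), and lp_0129 had a log2 value of 0.77 ± 0.30 that did not pass. Adjusted over the list alone, all 3 rose, and with the replicate block over control and shock cultures lp_0129 passed over all loci too (log2 0.77, limma with Benjamini-Hochberg adjusted p = 0.0322, range over 37 alternatives 0.00152 to 0.819), as it did without arrays 9 and 11 at log2 0.95. The fit without arrays 9 and 11 called 1004 loci, 463 higher and 541 lower, 757 of them shared with the 767. The count was 0 without control culture 2 in limma, with 682 loci at an unadjusted p under 0.05, and 177, 181 and 229 without control culture 1, adapted culture 2 and array 12. With only the 4 cultures compared in the fit it was 555, against 602 at 10 min and 575 at 30 min, and without adapted culture 2 it was 181 against 522 and 552, so the order of the comparisons by count depends on the fit. With 1 culture or array left out, log2 ran from 2.71 to 4.93 for lp_3324, 1.82 to 4.22 for lp_0995, −5.23 to −2.78 for lp_0263 and −4.56 to −2.50 for lp_0262. It ran from 1.58 to 2.54 for lp_2668, 1.00 to 3.05 for lp_3352 and 0.12 to 1.68 for lp_0129. Without background correction lp_3324 was at log2 2.73, lp_0995 at 2.15, lp_0263 at −2.34 and lp_0262 at −2.11, and these 4 still passed. All named calls ended without control culture 2, those of lp_3324, lp_0995 and lp_3352 also without adapted culture 2, those of lp_0995, lp_2668 and lp_3352 without array 12, and that of lp_0995 without control culture 1 or either 10-min culture.

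Adapted cultures were also compared directly with the 30-min shock, a comparison in which culture mode and growth stage may differ as well as the length of exposure. They differed at 388 loci, 183 higher and 205 lower in the adapted cultures. The loci lp_3514 (log2 2.87 ± 0.47, limma with Benjamini-Hochberg adjusted p = 0.0157) and lp_0995 (2.47 ± 0.53, adjusted p = 0.0283) rose the most. The largest falls were at lp_0423 (log2 −2.95 ± 0.32, limma with Benjamini-Hochberg adjusted p = 0.0109) and lp_0836 (−2.43 ± 0.59, adjusted p = 0.0374). Both adapted cultures lay on the same side of both 30-min cultures at these loci, as the rule requires. Of the small heat shock loci, lp_2668 was higher in the adapted cultures (log2 1.88 ± 0.26, limma with Benjamini-Hochberg adjusted p = 0.0124) and lp_0129 lower (−1.34 ± 0.30, adjusted p = 0.0309), while lp_3352 had a log2 value of −0.27 ± 0.24. The same 2 passed when adjusted over the list alone, 1 in each direction. Without arrays 9 and 11 the count was 603, with 301 higher and 302 lower and 381 shared with the 388. It was 0 in limma without either 10-min culture, adapted culture 1, array 2 or array 12 (859, 840, 1019, 750 and 658 loci at an unadjusted p under 0.05), and 14 without control culture 1. Of 37 alternatives, 11 ended the call of lp_3514, 14 that of lp_0995, 8 that of lp_0423, 17 that of lp_0836, 16 that of lp_0129 and 10 that of lp_2668. With 1 culture or array left out, log2 ran from 2.39 to 3.61 for lp_3514, 1.55 to 3.78 for lp_0995, −3.29 to −2.57 for lp_0423, −2.78 to −1.93 for lp_0836, −2.09 to −0.68 for lp_0129 and 1.41 to 2.38 for lp_2668. Without background correction the calls of lp_3514 (log2 1.73), lp_0995 (2.04), lp_0836 (−2.09) and lp_0129 (−0.90) ended and lp_0423 stood at −1.69, and without the dye term those of lp_0836 (−2.42) and lp_0129 (−1.31) ended with little change in value.

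**Figure D4:**
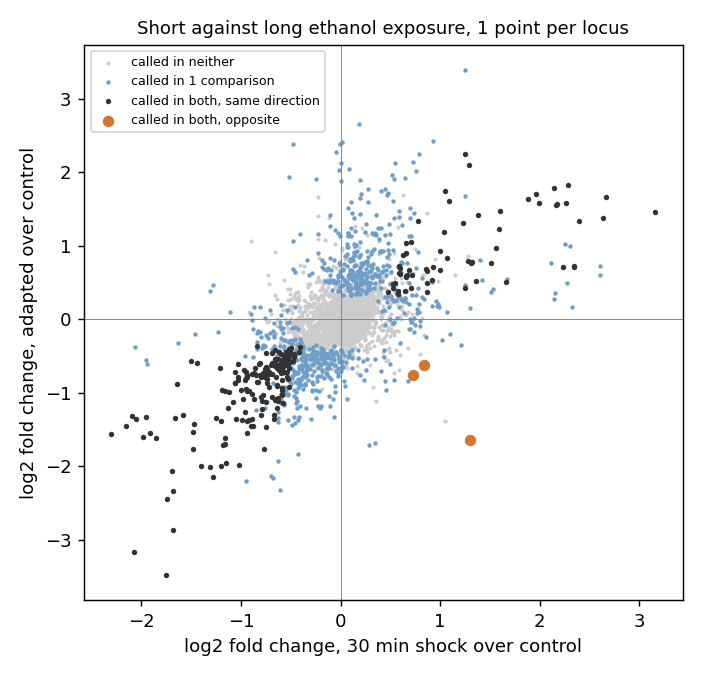
Log2 fold change of adapted over control (vertical axis) against that of 30-min shock over control (horizontal axis), 1 point per locus, with loci called in neither (grey), in 1 (blue) or in both comparisons in the same (black) or the opposite direction (orange). Most loci called in both lie in the same direction, 63 higher and 168 lower, and 3 lie in opposite directions.

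Across loci the fold changes of 30-min shock over control and adapted over control correlated at Pearson r = 0.57 and Spearman rho = 0.53. Simulated unchanged groups with shared controls, but without shared arrays, gave r = 0.50. The covariance was 0.154, against 0.0152 in the simulation. Both comparisons called 63 loci as higher, where independent lists would share 17.2, and 168 as lower, where they would share 35.7. Without arrays 9 and 11 these were 152, where 47.7 would be shared, and 307, where 84.8 would be. The control cultures were not split here either, so part of the excess may come from them or from error of shared arrays. From the 10 other arrays r was 0.66. Without array 8 the correlation was 0.28 and without control culture 2 it was 0.38.

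**Figure D5:**
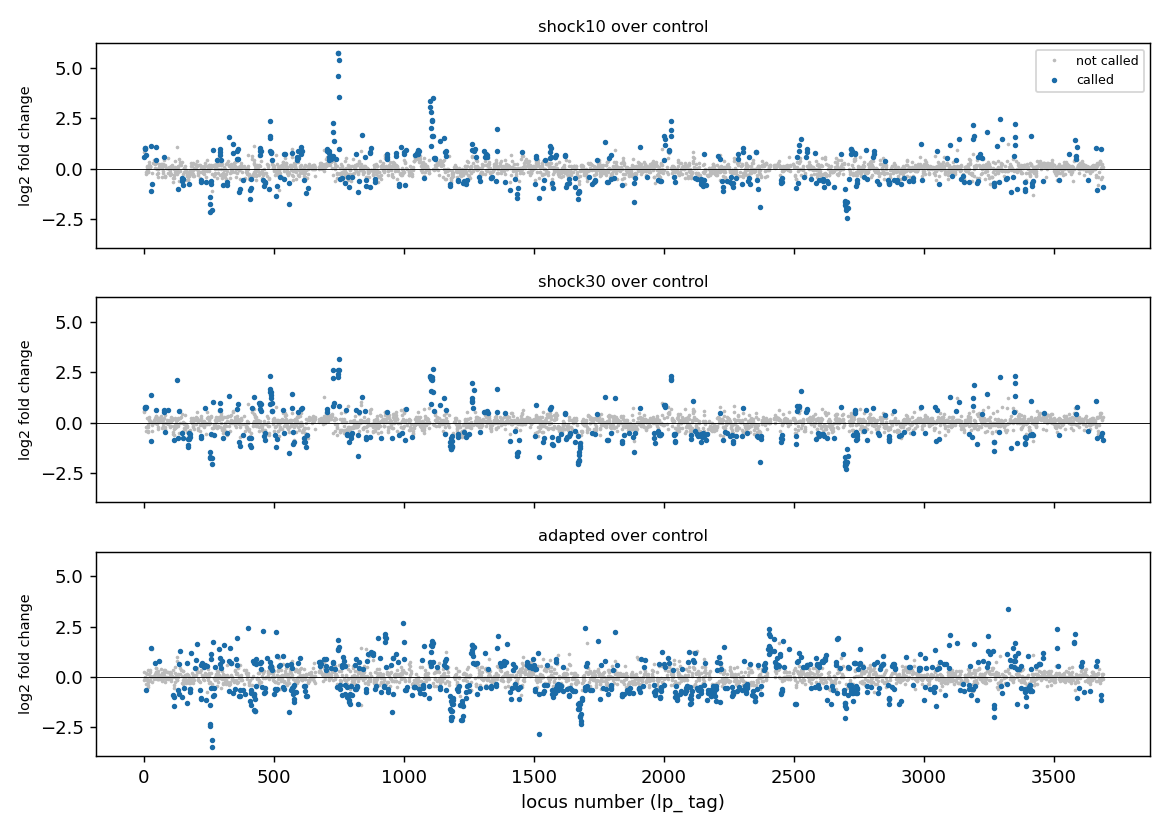
Log2 fold change over control (vertical axis) of each locus with a 4-digit tag against its tag number (horizontal axis), for 10-min shock (top), 30-min shock (middle) and adapted cultures (bottom), with loci at adjusted p under 0.05 in blue and others in grey. Several groups of adjacent loci change together, among them lp_0746 and lp_0747 at 10 min, at log2 5.77 and 5.73.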

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

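All tests on arrays 9 and 11 in this part were chosen after the results were seen.

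Array 9, labelled 30-min shock 1 over 30-min shock 2, had ratios as widely spread as arrays that joined different conditions. A difference between those 2 cultures is argued against by the other 10 arrays, whose ratio for them correlated with array 9 at r = −0.142, and noise of 1 array by probes of the same locus, which correlated at r = 0.57 over 2675 loci. A mislabelled sample stays open as a candidate explanation: the ratios correlated at r = 0.875 with the mean of adapted 1 and adapted 2 minus 30-min shock 2, so the Cy5 RNA may have come from an adapted culture. Taken singly, r was 0.937 for adapted 2, 0.663 for adapted 1 and at most 0.235 for any control or 10-min culture. No sample was moved to another condition on this basis.

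Array 11, the labelled dye swap of array 10, did not mirror it. Against the 10-array ratio of 30-min shock 2 over 10-min shock 2, r was −0.126, which argues against correct labels, and with the dyes exchanged the same test reads 0.126, which is too low for exchanged dyes alone. The ratios correlated at r = 0.953 with the mean of control 1 and control 2 minus 10-min shock 2, so a control culture as the Cy5 RNA may be the source. With each control singly r was 0.937 and 0.947, too close to tell the cultures apart. No biological explanation was tested for this array, since both labels name 1 pair of samples.

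The test of 30-min against 10-min shock differed at 4 loci (lp_0746, lp_0747, lp_0748 and lp_0749), which shows that the effects at the 2 time points were not equal there. Without arrays 9 and 11, 117 loci differed, 40 higher and 77 lower, with these 4 among them.

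Adapted cultures and the 30-min shock differed at 388 loci in the direct test. This count was 603 without arrays 9 and 11 and 143 without background correction. It was 0 in limma with the 4 cultures alone, with each array as a replicate or with culture as a random effect.

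At 3 loci the 30-min shock and the adapted state moved in opposite directions from control, and the direct test separated them. These were lp_0423 (log2 1.30 ± 0.32 at 30 min and −1.65 ± 0.32 in adapted cultures), lp_1908 (0.73 ± 0.16 and −0.75 ± 0.16) and lp_3190 (0.84 ± 0.18 and −0.63 ± 0.18), chosen after their values were seen. Without arrays 9 and 11, 13 loci did so, and 7 moved the other way round. The direct test adds no separate support, since its fold change is the difference of the 2 over control and its call was required.

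Probes outside the locus set, 43 in number and used in no comparison, included 40 that exceeded the 95th percentile of the negative controls in both channels of all 12 arrays.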

How the results depend on the processing

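The alternatives without arrays 9 and 11 and the one with signal means were chosen after the data were seen, and the causes of the changes below were not tested. Over 37 alternatives, the 35 values of named loci gave 1295 results, of which 1101 kept direction and side of the threshold, 141 were no longer past it, 29 came past it and 24 changed direction. The 10-min rises of lp_0746 and lp_0747 passed under all 37. Direction changed only for listed heat shock loci at values that had not passed. For lp_2668 at 30 min over control (log2 0.00) it was −0.0300 without background correction, −0.00610 with median centring, −0.0155 without the dye term, −0.0137 with each array as a replicate and −0.0128 with culture as a random effect, and with 1 culture or array left out it ran from −0.45 to 0.39. Likewise it ran from −0.93 to 0.17 for lp_2668 at 10 min and from −0.30 to 0.76 at 30 over 10 min, from −0.00496 to 2.48 for lp_0129 at 10 min and from −0.11 to 2.31 at 30 over 10 min, and for lp_3352 from −0.30 to 1.15 at 30 over 10 min and from −1.05 to 0.80 in adapted over 30-min shock.

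For adapted over 30-min shock (388 loci) the count was 143 without background correction, 241 without the dye term, 218 with the replicate block over all conditions, 603 without arrays 9 and 11, and 0 in limma with the 4 cultures alone, with each array as a replicate or with culture as a random effect (682, 850 and 810 loci at an unadjusted p under 0.05). The 10-min count (425) was 281 with the replicate block over all conditions and 259 with culture as a random effect. The 30-min count (383) was 575 with the 4 cultures alone, 783 with each array as a replicate and 741 without arrays 9 and 11. The count of 30 over 10 min (4) was 117 without arrays 9 and 11. With the replicate block as well, the count was 566 for adapted over 30-min shock, 717 at 30 min and 115 at 30 over 10 min. With all arrays, the block over control and shock cultures changed, among named loci, no other call than those of lp_0129. Other alternatives kept counts within 1.5 times.

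Leaving out 1 culture moved adapted over control (767) between 0 and 767: 177 and 0 without control 1 and 2, 411 and 433 without 10-min 1 and 2, 410 without 30-min 1 and 181 without adapted 2. Adapted over 30-min shock ran from 0 to 236: 14 and 236 without control 1 and 2, 0 without either 10-min culture or adapted 1, 105 and 178 without 30-min 1 and 2, and 139 without adapted 2. The 10-min count ran from 8 to 522: 161 and 46 without control 1 and 2, 8 without 10-min 2, 233 without 30-min 2 and 188 without adapted 1. The 30-min count ran from 0 to 552: 100 and 42 without control 1 and 2, 237 without 10-min 2, 0 without 30-min 1 and 125 without adapted 1. For 30 over 10 min it ran from 0 to 4. Where limma gave 0, 107 to 1019 loci had an unadjusted p under 0.05. Correlations ran from 0.66 (without 10-min 2) to 0.93 for 10 with 30 min, and from 0.38 (without control 2) to 0.67 for 30 min with adapted, with 0.47 without 30-min 1.

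Leaving out 1 array gave 229 to 924 loci for adapted over control (508, 479 and 229 without arrays 6, 8 and 12) and 0 to 574 for adapted over 30-min shock (0, 255, 149, 169, 111 and 0 without arrays 2, 3, 4, 5, 7 and 12). It gave 30 to 658 at 10 min (658, 223, 250, 274, 150 and 30 without arrays 1, 2, 7, 8, 11 and 12), 0 to 562 at 30 min (138, 198, 160, 244 and 0 without arrays 2, 7, 8, 10 and 12) and 0 to 12 at 30 over 10 min (2, 12 and 0 without arrays 9, 11 and 12), with 93 to 750 loci at an unadjusted p under 0.05 where limma gave 0. Correlations ran from 0.82 to 0.91 and from 0.28 (without array 8) to 0.67, with 0.47 without array 6.

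Dye terms per slide, scanner-processed signals and list alternatives were not run. In every channel 2841 of 2851 loci exceeded the negative controls, but values depended on background correction.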

Other observations

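The test of chance order was chosen after the pattern was seen, and so were the groups of loci by tag; the test of array position was set before its result.

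Called loci often stood next to each other in tag number. At 10 min, 10 loci in a row from lp_1101 to lp_1113 rose over control, with a median log2 change of 2.39, and in the adapted cultures 13 in a row from lp_1177 to lp_1190 fell, with a median of −1.36. Without arrays 9 and 11 all 10 and all 13 were still called, with medians of 1.84 and −1.33. Adapted over control had 61 such runs of 3 or more loci, 19 rising and 42 falling, with 271 loci in them, and 10-min shock over control had 40, 22 rising and 18 falling.

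Neighbouring loci called in the same direction made 292 pairs in adapted over control, whereas the highest of 1000 shuffles of the order was 129 and their mean 103, so chance order is excluded by this test. Without arrays 9 and 11 there were 423 pairs, against a highest of 214. Position on the array is argued against by spots that lie side by side there but belong to loci over 10 numbers apart: their fold changes correlated at r = 0.003 over 8084 pairs, against 0.42 for loci adjacent in number. Shared transcripts of neighbouring genes may give such runs, a hypothesis that was not tested, since no map of transcripts is used here.

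Of the 38 loci whose tags carry the mark p3, 7 were lower and 1 was higher in adapted cultures than in control, with a median log2 change of −0.15, and without arrays 9 and 11 the counts were 10 and 3 and the median −0.13. As a group they did not pass in any of 5 comparisons: in adapted over control the adjusted p by limma's camera was 0.193 with the preset correlation of 0.01 and 0.723 with an estimated correlation.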
